A study of Homo sapiens with 28 samples.

How the data were processed

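The measurements came from U2OS cells, a human osteosarcoma line. RNA-seq of polyadenylated RNA compared 3 libraries from cells given a non-targeting siRNA (CTR) with 3 from cells given an siRNA against TANGO6 (KD). Chromatin immunoprecipitation with sequencing (ChIP-seq) gave 14 peak lists, each from 1 library. They covered FLAG-tagged TANGO6 at 37 and 43 °C, and RNA polymerase II (RNAPII) after control (siCt) or TANGO6 (siT6) siRNA. RPB1, the largest RNAPII subunit, was also profiled after DMSO or dTAG-13, a compound that in these cells leads to the degradation of TANGO6, at 37 and 43 °C. Antibodies recognised FLAG, the N-terminal part of RPB1, RPB2, and the Ser2- or Ser5-phosphorylated form of RPB1, per the labels. FLAG samples were doubly crosslinked and RNAPII samples were fixed with formaldehyde alone, per the labels' protocols. Input libraries had no file of their own among those used here.

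For RNA, the authors deposited 1 table of RPKM values, reads scaled to gene length and library size, for 28278 genes. TopHat, DESeq2 and the hg38 build are named in the submitters' processing notes, without roles or versions. The gene model, the counting, the use of strand and the library totals are not given in the sources used here. Reads shared by overlapping genes, by near-identical genes such as HSPA1A and HSPA1B, or by ribosomal protein genes and their pseudogenes could therefore not be separated. Low RPKM values in a gene were whole multiples of a common step, and whole reads were recovered for 20671 of the 20673 genes above 0 in at least 3 libraries. Each value was divided by what 1 read was worth in its library. A gene counted as whole when the ratio of each value to the gene's highest lay within 1e-11 of a fraction with a denominator of at most 200000, and all its fractions shared a denominator of at most 1000000. Of 3000 simulated genes with values that were no whole multiples, 0 passed with 3 libraries above 0 and 713 with 2. Genes above 0 in just 2 libraries were therefore left out of that count. The smallest whole numbers with these ratios were taken, which are too low where all of a gene's reads share a factor. The recovered reads came to 26880487 to 29964646 per library, with a median of 958 reads per gene and library among the genes tested.

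For ChIP-seq, the authors deposited peak lists with a score per peak, made in 2 formats. FLAG-TANGO6, RPB1, RPB2 and Ser5P lists of the siRNA experiment held MACS-style peak names and scores of at least 50. The Ser2P lists and the DMSO and dTAG-13 lists carried a lower-ranging score, and per the file headers each was paired with an input library. Bowtie, hg38 and dm3 are named in the submitters' processing notes, with no role or version. The caller's version, threshold, score quantity, read depth and, for the first format, control library are not given in the sources used here. Lists were compared only within a format, except for the share of TANGO6 peaks on RPB1 peaks. The score is the authors' and served only to rank peaks within a list.

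RNA was tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5). The 12482 genes with a mean RPKM of at least 1 were kept, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries of a group agreed within sampling noise, with a chi-square per gene of 7.19 to 13.2 on recovered reads. Gene lists (31) were fixed before the data were examined, as were the tests and the rule for named genes. The 30 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, a rotation test of a list on its own.

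The rule for named genes took TANGO6, the 6 largest rises and 6 largest falls past the threshold without overlap between groups, up to 3 members per list with the smallest p, and all RNAPII subunits. For each pair of peak lists it took the 5 protein-coding genes of at least 3 kb with the largest gain and the 5 with the largest loss of covered length, and for TANGO6 the 5 highest-scored peaks per list. Some genes that the rule took are not reported here.

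Peaks were compared with pandas 2.3.3 and numpy 2.4.6. A peak counted as shared when at least 1 bp lay in the other list. Wilson 95% intervals from scipy 1.17.1 cover counting error only. Genes came from a RefSeq table of GRCh38.p14, the same build as hg38, with 19974 positioned protein-coding genes. The table gives no strand, so a peak within 1 kb of either annotated gene end replaced the planned window around the transcription start. With 1 library per condition no ChIP difference was tested. The change of a gene list's mean cover was placed among 10000 random lists of genes of at least 3 kb. Random members were drawn from the 50 genes closest in cover in the first list, and the percentile is the share of random lists with a lower change. Members were not matched on RNA level or gene length, nor chosen to move together, so percentiles describe the lists and are not p-values. TANGO6 peaks were placed at random 100 times between the first and last peak of each chromosome.

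Scripts were tested on simulated data. With 200 of 12480 genes changed in each of 5 simulations of the KD and CTR comparison, 19.2% were recovered at a log2 change of 0.25, 87.2% at 0.5, 98.8% at 1 and 99.6% at 2. Of the calls, 6.95% were unchanged genes. All simulated genes had the same dispersion, and far fewer genes changed than the 42.04% called in the real comparison. These rates therefore do not carry over to the real calls. Camera found 10 of 10 shifted lists and called 0 of 290 unshifted ones. Simulated genes varied independently, whereas the estimated correlation of the real lists reached 0.705 (cytosolic ribosomal proteins). The simulation therefore does not give the rate of false calls for lists whose genes move together. Covered lengths of 3000 simulated intervals were all equal to a base-by-base count. List percentiles fell under the 5th for 4 of 100 unshifted lists and for 100 of 100 lists shifted by 8 points. Simulated cover was spread evenly, whereas real cover was mostly low. For RPB1 in DMSO at 37 °C its median was 1.65% among genes with cover there or in dTAG-13 at 37 °C. Percentiles were not tested on simulated cover of that kind.

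Alternatives fixed beforehand were other pseudocounts, filters, scalings and limma settings, the replicate number as a block, each library left out, and, for peaks, stricter overlaps, equal list lengths, higher scores and a 2 kb window. Added after the data had been seen were limma with voom weights on recovered reads, removal of the gene length trend, gene sets by change of covered length, a threshold of at least 2-fold, lists without the cell-cycle genes, and the window at gene ends.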

Results

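The data cover RNA levels and the genomic positions of TANGO6 and RNAPII in U2OS osteosarcoma cells. TANGO6 was lowered with an siRNA or removed with dTAG-13, and some cells were shifted from 37 to 43 °C, a heat shock. RNA had 3 control and 3 knockdown libraries with 26880487 to 29964646 recovered reads each. Each ChIP condition had 1 library, so differences between peak lists have no replicate check and carry no p-value. The depth of the ChIP libraries is unknown.

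The comparison of KD with CTR asked how RNA levels differed between cells given the TANGO6 siRNA and cells given the control siRNA. RNA was measured after siRNA alone, so effects of the TANGO6 loss cannot be told apart from other effects of the siRNA. TANGO6 (chromosome 16, 68843531 to 69085182, hg38) had 2.85 ± 0.206 RPKM in CTR and 0.437 ± 0.063 in KD (SD, n = 3 each), a log2 change of -1.84 (SE 0.0775, limma adjusted p = 2.457e-06). Its recovered reads were 399, 418 and 412 in CTR and 55, 71 and 61 in KD. Of 40 G1/S and DNA replication genes 38 fell, of 37 G2 and mitosis genes 36 fell, of 25 p53 targets 18 rose, and of 79 cytosolic ribosomal protein genes 36 rose. These lists were called by camera at a preset correlation, and had in that order an adjusted p = 0.5603, 0.7377, 0.6026 and 0.88 with an estimated correlation. The ribosomal protein list had 17 rises after each library was rescaled to equal sums, and an adjusted p of 0.07638 by fry. Of 12482 genes tested, 2489 rose and 2759 fell at an adjusted p under 0.05, and 108 rose and 150 fell by at least 2-fold.

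CRYGS, a lens crystallin gene on chromosome 3 (186538443 to 186544380), rose most, from 5.84 ± 0.529 to 58.1 ± 1.78 RPKM (log2 3.21, SE 0.0768, limma adjusted p = 3.046e-07). TNFRSF11B, which encodes the decoy receptor osteoprotegerin, rose by a log2 change of 2.62 and RGS16, a regulator of G-protein signalling, by 2.15. POLDIP2 and CPA4 rose by 2.07 and 1.95. FYTTD1, an mRNA export adaptor gene on chromosome 3 (197749533 to 197787596), had the largest fall on the log2(RPKM + 0.5) scale, from 15.9 ± 0.443 to 2.62 ± 0.382 RPKM (log2 -2.41, SE 0.09, limma adjusted p = 1.455e-06). In RPKM itself the fall of TANGO6 was larger, 6.52-fold against 6.09-fold for FYTTD1. GLO1, the glyoxalase gene, fell from 114.5 ± 2.03 to 26.4 ± 1.50 RPKM (log2 -2.10). PALM2AKAP2 followed at -1.95, and the RNA-binding protein genes PTBP3 and MBNL1 at -1.75 and -1.75. In the plot of RPKM per library, the 3 KD values of each of these genes lay apart from the 3 CTR values, which the rule for the largest rises and falls required.

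**Figure D1:**
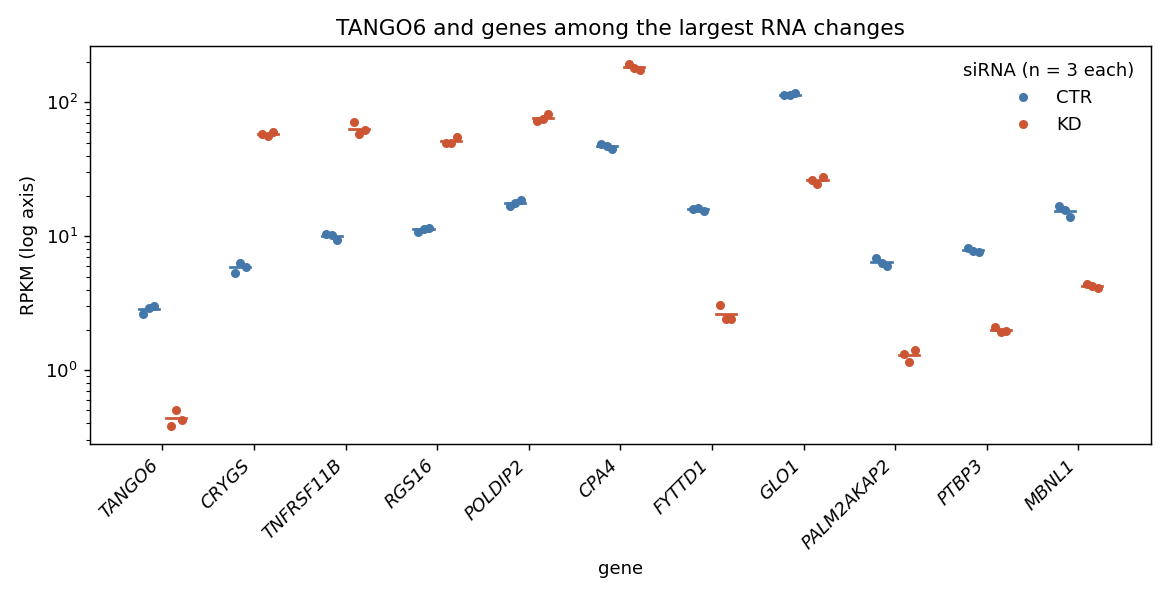
RPKM of TANGO6 and of genes among those with the largest rises and falls, on a log axis, in 3 CTR and 3 KD RNA libraries. Points are libraries and lines are group means; TANGO6 went from a mean of 2.85 to 0.437 RPKM and CRYGS from 5.84 to 58.1.

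Genes of the G1/S transition and DNA replication fell as a group, 38 of 40 at the threshold (38 also adjusted over the list alone), with a median log2 change of -0.59. The list had a camera adjusted p of 5.319e-17, and an adjusted p = 0.5603 with an estimated correlation. TYMS, the thymidylate synthase gene, fell from 143 ± 2.36 to 43.0 ± 3.05 RPKM (log2 -1.73, limma adjusted p = 2.27e-06). CDC6, which loads the replicative helicase, fell by 1.31 on the log2 scale, and MCM3, a helicase subunit gene, fell by 1.32. Of the 37 genes of G2 and mitosis, 36 fell (36 adjusted over the list alone), with a median of -0.46. Camera gave an adjusted p of 4.756e-13, and an adjusted p = 0.7377 with an estimated correlation. NUSAP1, a spindle protein gene, went from 109 ± 1.26 to 35.2 ± 2.86 RPKM (log2 -1.62), and ANLN, needed for cytokinesis, fell by 1.42 on the log2 scale.

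Targets of p53 rose, 18 of 25 measured, while 2 fell (18 and 2 adjusted over the list alone). The median log2 change was 0.41 (camera adjusted p = 3.869e-06, adjusted p = 0.6026 with an estimated correlation). CDKN1A, the gene of the cell-cycle inhibitor p21, rose from 49.9 ± 0.899 to 133 ± 6.78 RPKM (log2 1.40, limma adjusted p = 3.029e-06). CCNG1 and TP53INP1 rose by 1.54 and 1.35. The 2 that fell, named here after their values were seen, were MDM2, which encodes the ubiquitin ligase of p53, at -0.30 and the DNA polymerase gene POLH at -0.24.

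Of 79 cytosolic ribosomal protein genes measured, 36 rose, 0 fell and 43 were not called (41 and 0 adjusted over the list alone), with a median log2 change of 0.23 (camera adjusted p = 7.723e-08, adjusted p = 0.88 with an estimated correlation). By fry, which tests a list on its own, the adjusted p was 0.07638, above the threshold. The count of rises was 17 when each library was rescaled to equal sums. RPL13A rose from 622 ± 36.4 to 854 ± 46.7 RPKM (log2 0.46), and RPL41 and RPL10 rose by 0.52 and 0.35. Among 44 genes of ribosome biogenesis, 20 fell and 2 rose (22 and 2 adjusted over the list alone; median -0.19, camera adjusted p = 0.000452, adjusted p = 0.7377 with an estimated correlation). UTP4, a component of the small-subunit processome, fell by 1.05 on the log2 scale and TCOF1 by 0.50, while RRS1 rose by 0.81 and NOP53, named after its value was seen, by 0.34.

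Among 55 nuclear transport receptors and nucleoporins, 33 fell and 2 rose (35 and 2 adjusted over the list alone). Their median was -0.26 (camera adjusted p = 1.005e-06, adjusted p = 0.7377 with an estimated correlation). The importin gene IPO8 fell from 18.9 ± 0.355 to 8.36 ± 0.274 RPKM (log2 -1.13), and the nuclear pore genes NDC1 and NUP37 each fell by 1.05 on the log2 scale. KPNA6 and IPO13, also importin genes and named after their values were seen, rose by 0.66 and 0.55. Among 32 lysosome and autophagy genes, 14 rose and 3 fell (14 and 3 adjusted over the list alone; median 0.12, camera adjusted p = 0.02945, adjusted p = 0.88 with an estimated correlation). Without CTR replicate 2 that adjusted p was 0.05285. ATG5 and WIPI1, both autophagy genes, rose by 0.86 and 0.78, while LAMP1, a lysosomal membrane protein gene, fell from 202 ± 6.35 to 108 ± 4.399 RPKM (log2 -0.90). CTSL and UVRAG, named after their values were seen, fell to log2 changes of -0.33 and -0.36. Of 50 nuclear genes of oxidative phosphorylation, 5 rose and 1 fell (0 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.02945, adjusted p = 0.88 with an estimated correlation). Rescaling to equal sums, which multiplies all RPKM values of a library by 1 factor, gave 1 rise and 3 falls of oxidative phosphorylation genes and an adjusted p of 0.08822, while the list's median relative to that of all genes was 0.10 before and 0.10 after. Its adjusted p was also above the threshold by fry (0.2087), without CTR replicate 1 (0.06041), CTR replicate 2 (0.1622), KD replicate 2 (0.06435) or KD replicate 3 (0.1115), and with the gene length trend removed (0.2706). CYC1 and NDUFB5 rose by 0.27 and 0.25 and NDUFA8 fell by 0.44 on the log2 scale.

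**Figure D2:**
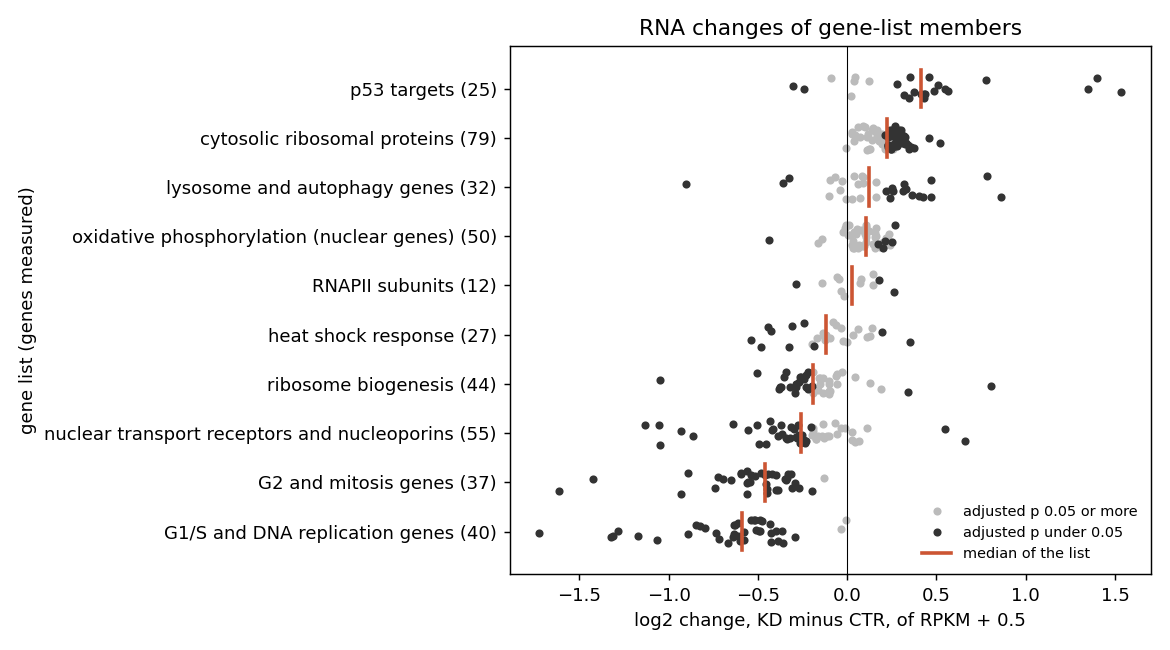
Log2 change (KD minus CTR, of RPKM + 0.5) of each measured member of 10 gene lists, with the number measured in parentheses. Dark points passed an adjusted p of 0.05 and the orange line is the list median; 38 of 40 G1/S genes and 36 of 37 mitosis genes were lower in KD, and 18 of 25 p53 targets were higher.

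Genes of RNAPII itself moved little. Of 12 subunit genes, POLR2G and POLR2C rose by 0.26 and 0.18, POLR2J fell by 0.28 on the log2 scale, and 9 did not pass the test (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.6657). Each of the 3 calls was lost in at least 1 of the other settings or with 1 library left out. POLR2A, the gene of RPB1, had 11.3 ± 2.02 RPKM in CTR and 10.2 ± 1.30 in KD, and POLR2B, the gene of RPB2, had 65.3 ± 2.21 and 62.8 ± 6.33. The log2 changes of POLR2D, POLR2E, POLR2F, POLR2H, POLR2I, POLR2K and POLR2L lay between -0.05 and 0.15, with the POLR2F value lowest and POLR2I highest.

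Other lists were not called by camera. Subunits of RNAPI and RNAPIII had 2 rises and 9 falls among 19 genes (2 and 9 adjusted over the list alone, camera adjusted p = 0.1413), with POLR3F falling by 0.81 on the log2 scale. RNAP assembly and import factors had 1 rise and 4 falls of 21 (1 and 4 adjusted over the list alone, adjusted p = 0.438), with URI1 falling by 0.40 on the log2 scale. Elongation and pausing factors had 3 rises and 8 falls of 28 (3 and 8 adjusted over the list alone, adjusted p = 0.2884), with LARP7, part of the 7SK particle, falling by 0.76 on the log2 scale. Mediator subunits had 3 rises and 2 falls of 32 (2 and 2 adjusted over the list alone, adjusted p = 0.6657), with a median of -0.01 and a mean of 0.01. Heat shock genes had 2 rises and 8 falls of 27 (2 and 7 adjusted over the list alone, adjusted p = 0.1413), with the chaperone genes FKBP4 and DNAJB6 falling by 0.54 and by 0.48 on the log2 scale. Proteasome genes had 10 rises and 2 falls of 36 (7 and 2 adjusted over the list alone, adjusted p = 0.05078), and passed with libraries centred on the median (adjusted p = 0.04521) and with voom (0.04439). With an estimated correlation in the main fit, camera gave the proteasome list an adjusted p = 0.88. After rescaling to equal sums proteasome genes had 6 rises and 4 falls (adjusted p = 0.09403), and with the length trend removed an adjusted p of 0.1143. Spliceosome genes had 0 rises and 7 falls of 34 (0 and 1 adjusted over the list alone, adjusted p = 0.07605). The spliceosome list passed after rescaling to equal sums (16 falls, adjusted p = 0.01734), with the length trend removed (9 falls, 0.02761) and with voom (14 falls, 0.04439). With an estimated correlation in the main fit, camera gave the spliceosome list an adjusted p = 0.88.

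Mitochondrial ribosomal protein genes had 11 rises and 7 falls of 74 (1 and 2 adjusted over the list alone, camera adjusted p = 0.6657), with MRPL39 falling by 0.80 on the log2 scale. Translation factors had 8 rises and 6 falls of 43 (7 and 5 adjusted over the list alone, adjusted p = 0.652). GSPT1, a translation termination factor gene, fell by 1.19 on the log2 scale and EIF3J rose by 0.61. ATF4 targets of the integrated stress response had 4 rises and 6 falls of 29 (4 and 6 adjusted over the list alone, adjusted p = 0.6022). Aminoacyl-tRNA synthetases had 1 rise and 2 falls of 20 (1 and 2 adjusted over the list alone, adjusted p = 0.7069). ER chaperone and unfolded protein response genes had 10 rises and 3 falls of 25 (10 and 3 adjusted over the list alone, adjusted p = 0.1413), with DNAJB9 rising by 0.99. COPI, COPII and Golgi genes had 8 rises and 5 falls of 36 (7 and 4 adjusted over the list alone, adjusted p = 0.5973), with SEC23A falling by 1.13 on the log2 scale.

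Among signalling lists, interferon response genes had 5 rises and 8 falls of 20 (5 and 8 adjusted over the list alone, camera adjusted p = 0.6657), with OASL rising by 0.96 and IFIT1 falling by 0.97 on the log2 scale. NF-kB and inflammatory genes had 5 rises and 3 falls of 11 (5 and 3 adjusted over the list alone, adjusted p = 0.2267), with CCL2 rising by 1.01. Immediate early genes had 2 rises and 5 falls of 19 (2 and 5 adjusted over the list alone, adjusted p = 0.2884), with FOS falling by 1.26 on the log2 scale. Extracellular matrix and osteogenic genes had 9 rises and 3 falls of 26 (11 and 3 adjusted over the list alone, adjusted p = 0.07808), with THBS1 and BMP2 rising by 1.17 and 0.97. Cholesterol synthesis genes had 5 rises and 3 falls of 24 (3 and 1 adjusted over the list alone, adjusted p = 0.6657), and glycolysis and hypoxia genes 5 and 4 of 29 (5 and 3 adjusted over the list alone, adjusted p = 0.6657).

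Rescaling to equal sums turned the balance of rises and falls in 7 lists that were not called with or without it. It gave 1 rise and 17 falls for mitochondrial ribosomal proteins, 6 and 9 for translation factors, 4 and 5 for COPI, COPII and Golgi genes, and 2 and 6 for cholesterol synthesis. Glycolysis and hypoxia genes then had 5 rises and 7 falls, Mediator subunits 2 and 3, and RNAPII subunits 0 and 1.

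Fry, which asks whether a list moves on balance one way and does not compare it with other genes, called 6 lists that camera did not. These were RNAPI and RNAPIII subunits (adjusted p = 0.007129), NF-kB and inflammatory genes (0.004986), immediate early genes (0.01168), extracellular matrix and osteogenic genes (0.01541), embryonic kidney and neuronal markers (0.03132), and elongation and pausing factors (0.04468).

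Markers of other cell types were measured for a foreign component. Epithelial markers had 1 rise and 1 fall of 8 (1 and 1 adjusted over the list alone, camera adjusted p = 0.7404), with a median of -0.01 and a mean of 0.16. CLDN4 rose from 7.60 ± 0.695 to 25.6 ± 1.86 RPKM. Embryonic kidney and neuronal markers had 3 rises and 1 fall of 7 (3 and 2 adjusted over the list alone, adjusted p = 0.6657), and their median of -0.06 and mean of 0.09 differed in sign, with SOX2 rising by 1.56 and LIN28B falling by 1.13 on the log2 scale. Only 2 haematopoietic markers were measured, and CD68 rose by 0.87 while LCP1 had a log2 change of -0.18 (adjusted p = 0.09585). The 3 KD values did not overlap the 3 CTR values for 6626 genes (53.1%), where chance gives 10%. Rises were 47.4% of the calls, and 32.7% (1677 of 5127) after rescaling each library to equal sums, which moved the median of all genes by -0.07.

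The ChIP comparison of siT6 with siCt asked where RNAPII lay after TANGO6 siRNA. Genes of the cell cycle carried less RNAPII peak cover in the siT6 libraries and p53 targets more. RPB1 peaks covered 41.6% of the length of the average G1/S gene in siCt and 26.7% in siT6, with 33 of 40 genes lower, and 58.1% and 43.6% of G2 and mitosis genes, with 33 of 37 lower. For p53 targets, RPB1 cover was 39.3% and 50.3%, with 20 of 25 genes higher. No random list of the 10000 had a lower change than either cell-cycle list (percentile 0), and p53 targets stood at percentile 100.

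MCM3, among the 5 largest losses, had RPB1 peaks over 90.5% of its length in siCt and 17.2% in siT6. RPB1 cover of CDC6 was 54.8% and 21.9%, and of NUSAP1 57.0% and 13.4%. HMOX1, the haem oxygenase gene (chromosome 22, 35381096 to 35394207), was among the 5 largest gains, with 16.8% and 96.9%. TTYH3 had 0% and 98.3% by RPB1, although RPB2 peaks covered 85.5% and 97.5% and Ser5P peaks 77.6% and 94.9% of the gene. PLK3 and ITPRID2 had 24.3% and 97.1% and 22.2% and 91.9%. Losses also included ISLR, at 76.0% and 0%, and VSIG2, at 82.6% and 17.9%, both with 0% RPB2 and Ser5P cover in either library.

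RPB2 and Ser5P, the form of RNAPII phosphorylated early in the transcription cycle, were also lower on cell-cycle genes than on matched random lists and higher on p53 targets. G1/S genes went from 19.3% to 16.9% RPB2 cover (percentile 0) and from 14.6% to 12.5% Ser5P cover (percentile 0.15), where matched random lists gained a median of 3.93 and 2.27 points. G2 and mitosis genes had 19.2% and 18.9% RPB2 cover (percentile 0.06) and 18.2% and 13.9% Ser5P cover (percentile 0). Targets of p53 had 21.3% and 32.2% RPB2 cover (percentile 99.8) and 17.6% and 28.7% Ser5P cover (percentile 100). TNFRSF11B went from 6.11% to 99.6% RPB2 cover and RGS16 from 8.93% to 100%. LIF, a cytokine gene, had 0% and 100% RPB2 cover, although RPB1 peaks covered 100% in both and Ser5P peaks 75.8% and 91.7%. Nuclear transport genes had 23.5% and 21.2% RPB1 cover (percentile 0.33), 7.72% and 9.52% RPB2 cover (percentile 21.1) and 6.16% and 5.87% Ser5P cover (percentile 1.33). Cytosolic ribosomal protein genes had 64.4% and 73.1% RPB2 cover (percentile 98.75) and 64.8% and 68.5% Ser5P cover (percentile 66.34). Their RPB1 cover of 91.7% and 91.3% (percentile 82.1) was near its upper limit in both libraries.

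**Figure D3:**
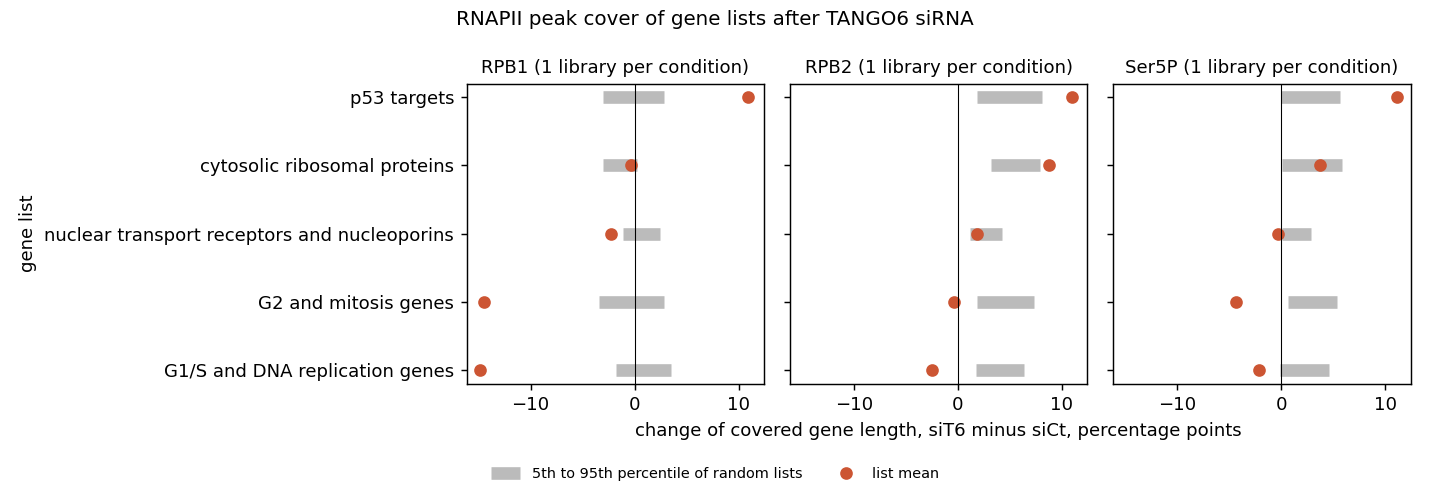
Change of the share of gene length covered by RPB1, RPB2 or Ser5P peaks (siT6 minus siCt, percentage points, 1 library per condition) for 5 gene lists. Points are list means and grey bars run from the 5th to the 95th percentile of 10000 random lists matched on siCt cover; RPB1 cover of G1/S genes was 14.8 points lower and of p53 targets 10.9 points higher.

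The lists of the siRNA experiment differed in size. RPB1 had 46197 peaks over 102 Mb in siCt and 47595 over 108 Mb in siT6, and 81.2% (Wilson 95% interval 80.8 to 81.5) of the siCt peaks were shared. RPB2 had 21763 peaks over 37.0 Mb and 27353 over 50.6 Mb, with 88.4% (87.98 to 88.8) shared. Ser5P had 18583 peaks over 30.6 Mb and 20358 over 39.1 Mb, with 85.2% (84.7 to 85.7) shared. Of protein-coding genes with a gene-end peak in siCt, 97.9% had one in siT6 for RPB1, 97.6% for RPB2 and 96.4% for Ser5P.

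Ser2P, the form of RNAPII phosphorylated during elongation, had fewer peaks in siT6, 9464 over 3.20 Mb against 16711 over 5.93 Mb, and 29.6% (28.9 to 30.3) of the siCt peaks were shared, or 19.4% with at least 50% of the peak covered. Cover was lower in siT6 for 77.5% of the genes with cover in either list. Ser2P peaks, in the other format, had median widths of 227 bp in siCt and 222.5 bp in siT6. Those of the RPB1, RPB2 and Ser5P siRNA lists were 1306 to 1529 bp, so shared percentages are not comparable between them and Ser2P. With unknown depth and 1 library per condition, a loss of Ser2P cannot be told apart from weaker peak calling in siT6. Immediate early genes stood apart, with 12.2% Ser2P cover in siCt and 2.70% in siT6 (percentile 0), and IER2 had 56.1% and 0%. CXCL14 had 73.2% and 2.20%. RGS16 and VGF were among the gains, at 0.590% and 28.9% and at 21.8% and 57.4%. G1/S genes stood at percentile 6.69.

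RNA changes were set against the peak changes. Genes with an RPB1 gene-end peak in siCt and none in siT6 had 34 falls and 11 rises in RNA among 79 measured, with a median log2 change of -0.16 against -0.01 in the background (camera adjusted p = 0.04598, adjusted p = 0.4785 with an estimated correlation). Genes with a Ser2P gene-end peak in siCt alone had 318 falls and 250 rises of 1332 (median -0.02 against 0.04 in the background, camera adjusted p = 0.01674, adjusted p = 0.4785 with an estimated correlation). Only 1 set was called without CTR replicate 1, CTR replicate 2 or KD replicate 3. Of the other sets, RPB1 gained had an adjusted p of 0.4645, RPB2 lost 0.1063, RPB2 gained 0.2577, Ser5P lost and Ser5P gained 0.07398 each, and Ser2P gained 0.1898.

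The FLAG ChIP asked where TANGO6 lay at 37 and 43 °C. Of the TANGO6 peaks, 78.2% at 37 °C and 74.2% at 43 °C overlapped a protein-coding gene, and many overlapped RNAPII peaks by at least 1 bp. At 37 °C there were 4454 TANGO6 peaks over 7.20 Mb and at 43 °C 11896 over 15.01 Mb. Of the 37 °C peaks, 74.5% (73.2 to 75.8) were shared with 43 °C, and of the 43 °C peaks 28.1% (27.3 to 28.9). With equal numbers of peaks taken from both lists these shares were 45.5% and 44.97%. RPB1 peaks of the DMSO cells at the same temperature held 78.9% (77.7 to 80.1) of the 37 °C peaks and 69.5% (68.7 to 70.3) of the 43 °C peaks, where random placements gave means of 2.93% and 2.28%. With at least 50% of the TANGO6 peak covered, these shares were 52.6% and 40.8%. With RPB1 peaks of the siCt library and an overlap of at least 1 bp the shares were 88.6% and 85.5%, against 6.82% and 6.00% at random. Random placements were not kept near gene ends, so they do not separate a relation with RNAPII from a shared position at gene ends.

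At 37 °C, 61.1% (59.7 to 62.5) of TANGO6 peaks lay within 1 kb of a gene end, and at 43 °C 54.5% (53.6 to 55.4). The highest-scored 37 °C peak lay on ZFP36L1 (chromosome 14, 68788550 to 68797989), a gene for an mRNA decay factor. Among the next 4 were peaks on PRAME (chromosome 22, 22556806 to 22560201) and IRF2BPL (chromosome 14, 77025096 to 77029788). At 43 °C the top 5 included peaks on BHLHE40 (chromosome 3, 4976754 to 4981095) and TNRC18 (chromosome 7, 5419483 to 5428330). Ranks 2 and 5 at 37 °C and ranks 1, 2 and 5 at 43 °C had no protein-coding gene under the peak or within 1 kb. Rank 1 at 43 °C (chromosome 17, 74513227 to 74515649) overlapped rank 5 at 37 °C (74513359 to 74515732). TANGO6 cover of heat shock genes was 4.70% at 37 °C and 8.13% at 43 °C (percentile 99.95), and of cytosolic ribosomal protein genes 3.39% and 9.99% (percentile 100). Over all genes of at least 3 kb with TANGO6 cover in either list, mean cover went from 2.19% to 3.96%. Random lists were matched on 37 °C cover alone, not on RNA level or gene length. The percentiles therefore do not show a gain particular to these lists. CCN2 and GAS1 were among the largest gains, from 0% to 54.5% and from 0% to 51.0%, and MDK and SEPTIN5 among the largest losses, from 48.9% and 44.1% to 0%.

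The dTAG-13 series asked how RPB1 responded to heat with TANGO6 present or degraded. Heat shock genes had more RPB1 cover at 43 °C in both, and cytosolic ribosomal protein genes had less. The 24 heat shock genes of at least 3 kb had a mean RPB1 cover of 13.5% at 37 °C and 46.5% at 43 °C in DMSO, and 8.44% and 43.2% in dTAG-13 (percentile 100 each). BAG3, a co-chaperone gene, had 2.30% and 91.3% in DMSO and 1.30% and 89.9% in dTAG-13. HSPH1, an HSP110 chaperone gene, had 3.03% and 47.3% in DMSO and 1.16% and 46.4% in dTAG-13. Cytosolic ribosomal protein genes had 44.5% and 17.9% in DMSO (percentile 0) and 29.98% and 18.8% in dTAG-13 (percentile 0.38), and RPL12 had 100% and 16.9% in DMSO and 95.6% and 14.9% in dTAG-13. Random lists were matched on 37 °C cover alone, so these percentiles do not separate the lists from other genes of like RNA level or length. Whether the heat responses differed between DMSO and dTAG-13 was not tested.

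**Figure D4:**
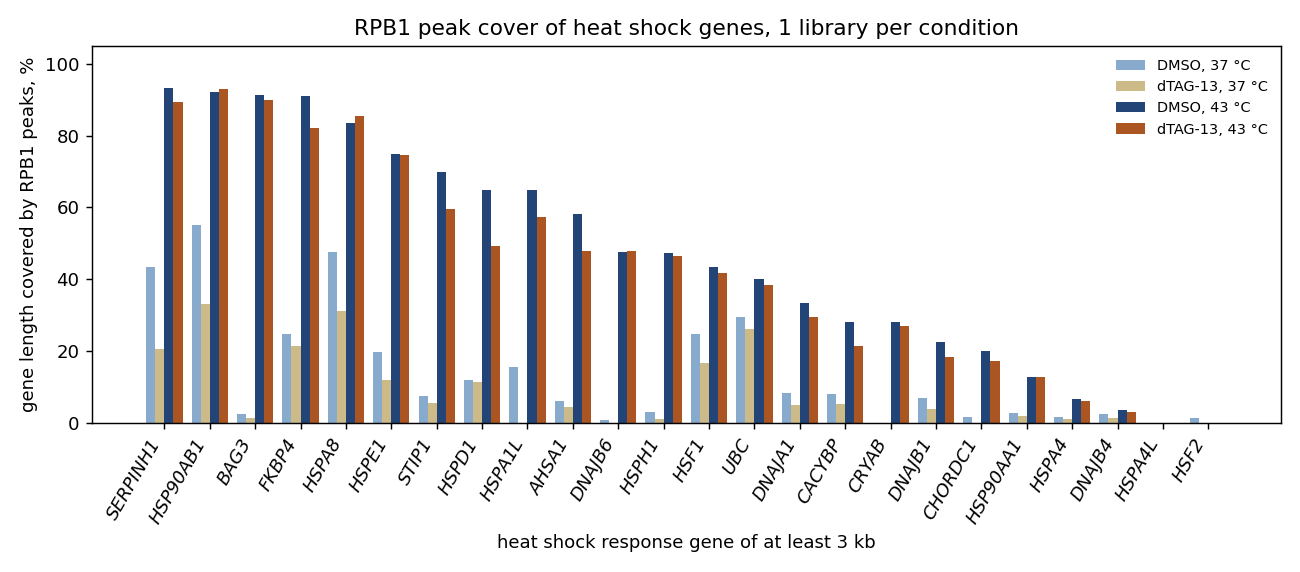
Share of gene length covered by RPB1 peaks (percent) for the 24 heat shock genes of at least 3 kb, in DMSO and dTAG-13 cells at 37 and 43 °C. Bars are single libraries; BAG3 went from 2.30% to 91.3% in DMSO and from 1.30% to 89.9% in dTAG-13.

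Among the genes with the largest gains at 43 °C were MKNK2, CLDN19, FOSB, BAG3 and PGF in DMSO, and FOSB, MKNK2, CLDN19 and RNF223 in dTAG-13. FOSB, an immediate early gene, had 0% and 89.1% RPB1 cover in DMSO and 4.11% and 100% in dTAG-13. YPEL4 lost most, from 98.6% to 0% in DMSO and from 91.0% to 0% in dTAG-13. Immediate early genes as a list had 36.8% and 45.9% in DMSO and 30.5% and 44.6% in dTAG-13 (percentile 100 each).

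At 37 °C, dTAG-13 cells had fewer RPB1 peaks than DMSO cells, 32826 over 12.7 Mb against 44366 over 19.6 Mb. Of the DMSO peaks 48.0% (47.6 to 48.5) were shared, and RPB1 cover was lower for 81.9% of genes with cover in either list. Cytosolic ribosomal protein genes stood at percentile 1.23, from 44.5% to 29.98%, and G1/S genes at percentile 90.94, from 11.8% to 9.13%. GFER had the largest loss, from 88.8% to 29.0%, and SLC5A2 the largest gain, from 2.68% to 23.9%. At 43 °C the lists were closer in size, 39952 peaks over 17.4 Mb with dTAG-13 and 41818 over 19.2 Mb with DMSO, and 60.3% (59.8 to 60.7) of the DMSO peaks were shared. Heat shock genes had 46.5% RPB1 cover in DMSO and 43.2% in dTAG-13 at 43 °C, the 5th percentile of random lists. CIMIP2A had the largest gain, from 50.8% to 89.4%, and ACY1 the largest loss, from 58.1% to 25.8%.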

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

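The test of weaker peak calling below was chosen after the result was seen. The number of RPB1 peaks moved in opposite directions with heat in the DMSO and dTAG-13 cells. At 43 °C the DMSO list held 2548 fewer peaks than at 37 °C (a difference of -2548) and the dTAG-13 list 7126 more. Covered length differed by -0.3371 Mb in DMSO and by 4.7644 Mb in dTAG-13. The difference between these responses was not tested, as each condition had 1 library.

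The dTAG-13 differences start from its list at 37 °C, which held 32826 peaks against 44366 in DMSO. Weaker peak calling in that library, from depth or enrichment, would remove low-scored peaks first. Of the 10% of DMSO peaks with the highest scores, 0.0451% were missing from the dTAG-13 list, and of the lowest 10%, 84.4%. Of the 32826 dTAG-13 peaks, 8501 shared no base with a DMSO peak. The order by score leaves weaker calling open but cannot establish it. Fewer polymerases on every gene could give the same order, and the depth of these libraries is unknown. A loss of RNAPII after TANGO6 degradation therefore cannot be told apart from weaker calling.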

How the results depend on the processing

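Voom, the gene length trend, lists without cell-cycle genes, the 2-fold threshold, the gene-end window and sets by cover change were added after the data had been seen. The number of genes called ran from 3885 (mean RPKM of at least 5) to 5714 (voom), with no reversed gene, and from 4043 to 4761 with 1 library left out. Of 1857 values of named genes under other settings, 1823 stayed on their side of the threshold and 34 lost it. Of 104 adjusted p-values of called lists, 88 stayed under 0.05. By fry 12 lists were called, without the cytosolic ribosomal protein and oxidative phosphorylation lists. Lists without cell-cycle genes gave the same 8 calls, a setting that moves nothing because no other list shares those genes.

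With an estimated correlation, 0 gene lists, 0 peak-change sets and 0 cover-change sets were called, and the cause was not tested. With 1 library left out, 1 to 3 peak-change sets were called: 1 without CTR replicate 1, CTR replicate 2 or KD replicate 3.

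With the replicate number as a replicate block, 4916 genes were called. Deviations of same-numbered libraries correlated at -0.03, 0.13 and 0.08, and CTR replicate 1 correlated best with KD replicate 3 (0.15). These few correlations do not show whether the numbers pair samples.

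Shares of the first list found in the second moved in all 9 pairs, and the cause was not tested. With 50% of a peak covered they were 70.7% (TANGO6), 77.3% (RPB1 siRNA), 86.2% (RPB2), 83.5% (Ser5P), 19.4% (Ser2P), 37.6% (dTAG-13 against DMSO at 37 °C), 51.2% (at 43 °C), 32.7% (43 against 37 °C, DMSO) and 38.4% (dTAG-13). With equal numbers of peaks they were, in that order, 45.5, 80.5, 84.0, 82.9, 40.7, 59.7, 61.8, 42.9 and 44.1%, and in the upper 50% by score 67.3, 89.4, 94.7, 90.4, 32.1, 60.4, 71.9, 52.0 and 58.8%. TANGO6 peaks on RPB1 peaks of DMSO cells were 52.6% (37 °C) and 40.8% (43 °C) with 50% covered, and 88.1% and 83.5% in the upper 50% by score. The shares of genes with gene-end peaks in both lists stayed within their intervals for 9 of 9 pairs. The unknown ChIP depth limits every difference in peak number.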

Other observations

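The gene sets by change of RNAPII cover and their splits were chosen after the result was seen. Lower Ser2P cover in siT6 went with lower RNA for some genes and higher RNA for others. JUND, an immediate early gene, had Ser2P peaks over 57.0% of its length in siCt and 0% in siT6, and its RNA fell by 0.81 on the log2 scale. IER3, of the NF-kB list, had 52.0% and 6.15%, and its RNA rose by 0.67. CDKN1A had 42.5% and 59.4%, with RPB1 cover of 99.6% and 100%. Among the largest falls in RNA, RPB1 cover in siCt and siT6 was 5.86% and 3.23% for FYTTD1, 12.1% and 4.43% for GLO1, 1.73% and 1.79% for PTBP3 and 2.82% and 1.98% for MBNL1. It was 0.673% and 1.23% for PALM2AKAP2 and 0.460% and 0.858% for TANGO6. TYMS, whose RNA fell by 1.73 on the log2 scale, had 75.8% and 76.0%.

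Genes whose cover differed by at least 20 points between siCt and siT6 were tested in the RNA. The 245 measured genes with more RPB1 cover in siT6 had 103 rises and 21 falls (median 0.17, camera adjusted p = 9.639e-08), and the 163 with less had 15 rises and 79 falls (median -0.21, adjusted p = 2.951e-06). Genes with more RPB2 cover had 142 rises and 29 falls of 403 (adjusted p = 2.442e-07), and with more Ser5P cover 111 and 16 of 259 (adjusted p = 2.435e-08). Each of these 4 sets had an adjusted p = 0.1892 with an estimated correlation. Sets with less RPB2, Ser5P or Ser2P cover had an adjusted p of 0.6478, 0.2014 and 0.4601. Across genes, which are not independent replicates, the change of cover after siRNA was set against the change of RNA after siRNA. Spearman rho was 0.229 for RPB1, 0.207 for RPB2, 0.211 for Ser5P and -0.0351 for Ser2P. The change of RPB1 cover from DMSO to dTAG-13, set against the same change of RNA after siRNA, had a rho of -0.11. No RNA was measured after dTAG-13, so this last value joins different treatments and does not show how RNA responded to dTAG-13.

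The fall of G1/S genes was weighed against gene length and against less RNAPII on these genes. A length trend was argued against as the whole cause, since the median went from -0.5898 to -0.5759 with the trend removed (adjusted p = 3.149e-17). Less RNAPII after TANGO6 siRNA is a candidate explanation: the highest percentile of the list's cover change was 0.15 over RPB1, RPB2 and Ser5P. Its prediction was written with the RPB1 value of MCM3 already seen, and without MCM3 the highest percentile was 0.34. The random lists were matched on siCt cover alone, not on RNA level or gene length. Ser2P stood at 6.69 and RPB1 after dTAG-13 at 90.94, each condition had 1 library, and a slower cell cycle from any cause stays open, as untested.

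The rise of cytosolic ribosomal protein genes was weighed against gene length and against a rise of abundant transcripts. With the length trend removed the median went from 0.2251 to 0.1653 (camera adjusted p = 4.594e-05 at the preset correlation), which argues against length alone as the whole cause. Of 10000 random lists matched on mean RPKM, 0.01% reached the list median, and the random lists also had a positive median of 0.129. Random members were matched on mean RPKM alone, whereas the genes of this list moved together (estimated correlation 0.705). The share of random lists therefore does not decide whether abundance was the whole cause. Length and abundance were not removed together. Counting of reads from pseudogenes stays open, since the counting is not given in the sources used here.

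The 6 RNA libraries make 10 splits of 3 against 3, too few for a share under 0.05. Every other split mixes CTR and KD libraries on both sides. It keeps part of the difference between KD and CTR and adds the rest to the spread. Counts from the other splits therefore do not show what would be called without an effect. The real split called 5248 genes and the highest other 0, so 1 split gave as many genes. For gene lists the values were 8 and 11, with 6 splits giving as many lists. For peak-change gene sets they were 2 and 2, with 3 splits giving as many, and for peak-cover-change sets 4 and 5, with 8 splits giving as many.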
